A study of Mus musculus with 6 samples.

How the data were processed

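The series holds 6 Affymetrix GeneChip Mouse Gene ST arrays of cultured lacrimal gland myoepithelial cells, 3 from TSP1 null and 3 from wild-type female mice. Per the labels' protocols, exorbital glands were minced and digested with collagenase, the cells were kept in serum-containing medium for about 2 to 3 weeks, total RNA was extracted with Trizol, and 150 ng was labelled with biotin. Groups and replicate numbers were taken from the sample titles. The titles write the null group with a spelling that reads as TSP1-1, and the source names call the same samples TSP1 null.

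The authors deposited log2 signals of 41345 probe sets per array, already normalized across arrays. Per the submitters' processing notes, Partek and RMA (background correction, quantile normalization and summary of the probes of a set) were used. Their versions and settings, and any genome build, are not given in the sources used here. The log2 scale was read from the values, which run from about 1.83 to 14.2 with nearly equal quartiles on every array. RMA signals have a floor set by background, so differences of dim probe sets are compressed. Raw scanner files were not used here. No array repeated another, since correlations between arrays ran from 0.978 to 0.992. Of the deposited probe sets 1398 repeat the values of another, 968 of them without a symbol, and 0 tested genes do.

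Probe sets were named from the platform's annotation table. It gave exactly 1 gene symbol for 23521 probe sets, several for 1814 and none for 16010. Through Entrez identifiers 23328 of them matched the reference gene table (assembly GRCm38.p6), and 0 symbols changed. Probe sets with 1 symbol were tested, and for the 1082 genes with more than 1 probe set the one with the highest mean over the 6 arrays was kept, which left 22180 genes. No intensity filter was used. Control probe sets could not be told from other unnamed ones, so the alternative on every deposited probe set includes them. No coordinates are given, because the build behind the probe sets is not named, and the reference table was used for names and gene order only.

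The groups were compared with limma's lmFit and eBayes (default prior, two-sided) on all 6 arrays without covariates, as null minus wild type, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors are limma's SE of the difference for genes and, for lists, the SE of the difference between the group means of the list's mean per array. Gene lists (31, with 567 genes, 525 of them measured) were fixed from knowledge of the tissue, of TSP1 and of other cell types a gland culture could hold. Of these, 30 were tested with camera at its preset correlation of 0.01 and adjusted over the 30 lists, and the sex-linked list was kept as a check of the samples. Beside it stand camera with an estimated correlation, fry, and an exact permutation test of the list mean, two-sided, whose smallest p is 0.1. Members were also adjusted over the list alone. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the figures.

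The genes named in the report followed a rule. It took Thbs1; the 10 genes per direction with the largest difference among those past the threshold with no overlap between groups, filled up with the genes of smallest p where fewer passed; up to 4 members of each study or process list and up to 2 of each cell type list past the threshold, or the 2 members of smallest p where fewer than 2 passed; and Acta2, Cnn1, Oxtr, Chrm3, Tgfb1 and the sex-linked genes. As 0 genes passed, all top genes are those of smallest p. Symbols of predicted or uncharacterised loci were left out. Members that passed adjusted over the list alone, Tagln and the genes singled out in the closing section were added after their values were seen. The design, the lists, this rule and the alternatives were chosen before the data were examined, except where the text says otherwise.

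The procedure was tested on simulated data with 22180 genes and 3 arrays per group in 20 runs. It recovered 67.6% of genes changed 2-fold and 95.9% of those changed 4-fold, with 4.55% of its calls false, and it called a list shifted by 0.5 in all 20 runs. The simulated genes vary independently, which real genes do not. The median SE of a gene's difference in the real data was 0.14.

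Alternatives were quantile normalization, centring each array on its median, leaving out dim probe sets, averaging probe sets per gene, testing every deposited probe set, an intensity trend with a robust prior, array weights, the replicate number as a block, a minimum of 1.5-fold, an ordinary linear model, other forms of camera, other numbers of neighbours of Thbs1, and leaving out each array in turn. Alternatives added after the data were seen were the fit without the second null and the first wild-type array together, the macrophage list mean as a covariate, and the neighbours counted at an unadjusted p.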

Results

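Total RNA from cultured myoepithelial cells of the mouse exorbital lacrimal gland was profiled on 6 Affymetrix Mouse Gene 2.0 ST arrays. Myoepithelial cells are the contractile basal cells that wrap the secretory acini of the gland. The cells came from female mice that were either TSP1 null (3 arrays) or wild type (3 arrays), and were grown for about 2 to 3 weeks without treatment. TSP1 is thrombospondin-1, a secreted matrix glycoprotein encoded by Thbs1, and the series uses the null mouse as a model of dry eye disease, so the comparison asks how gene expression in these cells differs between the model and healthy mice. Each array gave 41345 log2 signals with a median between 5.25 and 5.32, and 22180 named genes were compared as TSP1 null minus wild type. Arrays have no sequencing depth, so their number limits the precision. The labels call the arrays of a group biological replicates without stating whether each had its own culture or animal, so p-values measure the spread between these arrays.

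The targeted gene, Thbs1 (probe set 17374488), had log2 signals of 12.73, 13.03 and 13.00 in the TSP1 null arrays and 13.51, 13.75 and 13.54 in the wild-type arrays. The difference was -0.68 (SE 0.13, n = 3 per group), or 0.626-fold, with every null array below every wild-type array. Over all genes tested it did not pass the limma threshold (adjusted p = 0.25). The signal stayed among the brightest on the null arrays. Where the probes lie relative to the disrupted part of Thbs1 is not given in the sources used here, so the gene is a weak check of the labels. Its relatives Thbs2 and Thbs3 had higher means in the null group. Thbs2 measured 11.96 ± 0.15 against 10.95 ± 0.30 (SD, n = 3), a difference of 1.01, and Thbs3 measured 7.86 ± 0.05 against 7.35 ± 0.14.

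Cultures from TSP1 null mice had higher signals for glycolysis and hypoxia genes (mean log2 difference 0.78, SE 0.21, n = 3 per group), basement membrane genes (0.48, SE 0.06) and fibrillar collagen and matrix genes (0.30, SE 0.16). Their signals were lower for macrophage markers (-1.39, SE 0.76), cell cycle genes (-0.42, SE 0.37) and cholesterol synthesis genes (-0.39, SE 0.19). The 95% intervals of the macrophage (-3.49 to 0.72) and cell cycle shifts (-1.46 to 0.61) included 0. So did those of the cholesterol synthesis (-0.91 to 0.14) and fibrillar matrix shifts (-0.13 to 0.73). Those of the glycolysis and hypoxia (0.19 to 1.37) and basement membrane shifts (0.32 to 0.63) did not. Levels of the macrophage, cell cycle and fibrillar matrix lists overlapped between the groups. Contractile genes, which myoepithelial cells share with smooth muscle, had a mean difference of 0.13 (SE 0.11) and were not called. Among them Acta2 measured 13.93 ± 0.07 in the null arrays and 13.98 ± 0.04 in the wild-type arrays (SD, n = 3). The 6 shifts are among 10 lists that limma's camera called with its preset correlation. In other divisions of the 6 arrays into 3 and 3 it called up to 13 lists this way. With an estimated correlation camera called 0 of the 10 lists, and no gene on its own passed the threshold over all genes tested.

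With limma, 0 of 22180 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.161. At an unadjusted p under 0.05 there were 2341 genes (10.6%), 1393 higher and 948 lower in the null group, where 1109 would be expected by chance. Of the 2341 genes, 686 differed by at least 1.5-fold, 248 higher and 438 lower. An ordinary linear model without moderation also called 0 genes and gave 1904 at an unadjusted p under 0.05. The 3 null and 3 wild-type arrays did not overlap for 3506 genes (15.8%), against the 10% that chance gives on average, with the same limit. The second null array decided the count of calls, since 34 genes passed without it, 15 higher (among them Angptl4, Pfkl, Slc2a1 and Egln3) and 19 lower (among them Ceacam1 and Cd59a), and without the first wild-type array 1 gene, Fabp7, passed.

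Among genes with higher signals, the smallest p belonged to Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, with a difference of 1.62 (SE 0.21, 3.07-fold, adjusted p = 0.161). Pfkl, a glycolytic phosphofructokinase, had a difference of 1.42 (SE 0.20, 2.67-fold, adjusted p = 0.178). The other 8 of the top 10 were Exd1 (33 genes from Thbs1 on its chromosome), Pbxip1, Emilin1 (an elastic fibre glycoprotein), Atp2b4 (a plasma membrane calcium pump), Ptprf (a receptor tyrosine phosphatase), Lrp5 (a Wnt co-receptor), Alkbh5 (an RNA demethylase) and Fbxl16, with differences from 0.65 for Fbxl16 to 0.86 for Ptprf. Among genes with lower signals, Ceacam1, a cell adhesion molecule, had a difference of -2.07 (SE 0.24, 4.20-fold lower), and Cd59a, which blocks the membrane attack complex of complement, had -1.85 (SE 0.23, 3.61-fold lower), each with an adjusted p of 0.161. Snora34, a small nucleolar RNA, had the smallest unadjusted p of all (7.45e-06) at a difference of -1.29. The remaining genes were Mmp27, P2ry13, Ints6l, Frrs1, Iqgap2, Mir5104 and Ttc32, from -1.39 for Mir5104 to -0.75 for Ttc32. Ints6l, which has 2 probe sets, had -0.98, and this ran from -1.06 to -0.52 over the alternatives. In each of these 20 genes the 3 arrays of 1 group lay entirely on the same side of the other group, which their choice by smallest p makes likely.

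**Figure D1:**
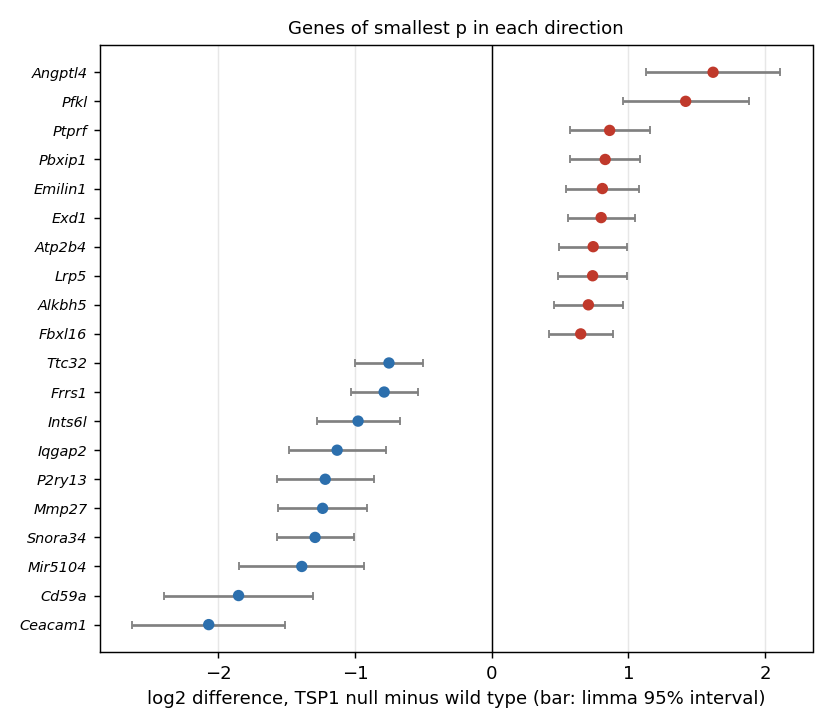
The log2 difference, TSP1 null minus wild type, of the 10 genes of smallest p in each direction, with bars for limma's 95% interval (n = 3 arrays per group). Differences ran from -2.07 for Ceacam1 to 1.62 for Angptl4, and the adjusted p of these genes was 0.161 or higher.

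Contractile smooth muscle genes were not called as a group. The mean difference of the 22 measured members was 0.13 (SE 0.11), 16 positive and 6 negative (camera adjusted p = 0.16). Acta2, the smooth muscle actin used to mark myoepithelial cells, had a difference of -0.05 (SE 0.10), Cnn1, which encodes calponin, 0.06 (SE 0.17) and Flna, an actin crosslinker, 0.42 (SE 0.12, adjusted p = 0.352). Lmod1 had a difference of 0.40 (SE 0.20), or 0.23 without the first wild-type array. No contractile gene passed over all genes tested, and 0 passed adjusted over the list alone. The basal epithelial list shifted by 0.14 (SE 0.14, 16 genes, adjusted p = 0.275) and was called at 0.24 without the third null array, but it was 0.072 without the second null array and 0.050 without the first wild-type array. Krt14, a basal keratin, was the only member to pass adjusted over the list alone, with 6.12 ± 0.30 against 5.23 ± 0.29 (SD, n = 3), while 0 passed over all genes. Krt17 had a difference of 0.82 (SE 0.23). Mean levels of the basal list on the null and wild-type arrays were 6.27 and 6.13, against 9.45 and 9.34 for fibroblast markers. Which cells of the cultures gave the contractile signal was not tested. Oxtr, the oxytocin receptor, and Chrm3, a muscarinic receptor, had differences of -0.05 (SE 0.18) and 0.02 (SE 0.17). The 29 genes of calcium and neurotransmitter signalling shifted by 0.02 (SE 0.10, adjusted p = 0.565), with 0 passing either way. Their smallest p values were those of Atp2a2, the endoplasmic reticulum calcium pump, at 0.35 (SE 0.10), and P2rx7, an ATP-gated channel, at -0.85 (SE 0.27), or -0.24 with the macrophage list as a covariate. The shift of the contractile list was called in 2 of 18 alternatives, at 0.19 without the first null array and at 0.27 with the macrophage list as a covariate, a term added after the data were seen. It was 0.045 without the second null array and 0.063 without the first wild-type array.

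**Figure D2:**
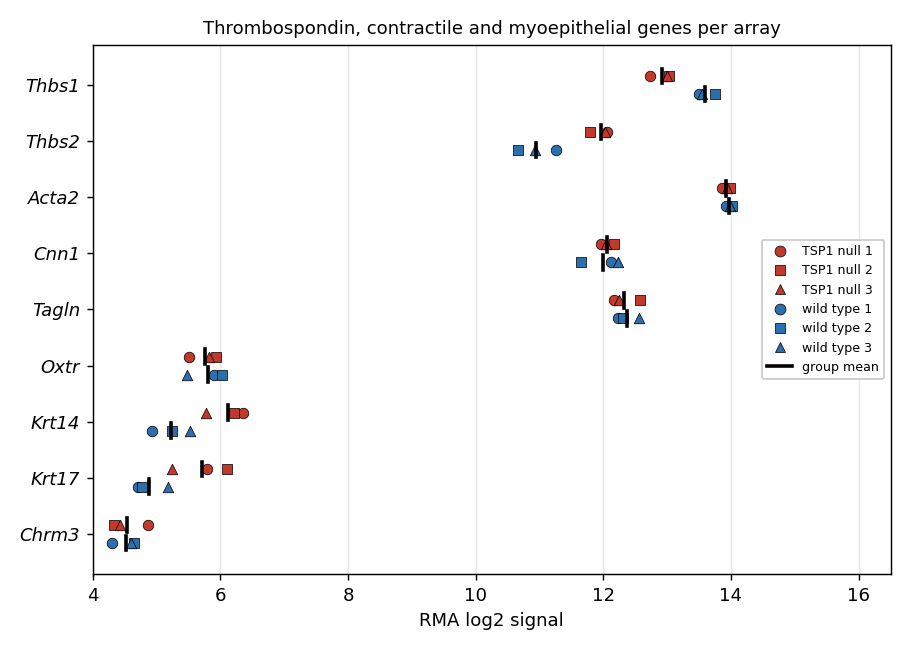
Log2 signal of thrombospondin, contractile and myoepithelial genes on each of the 6 arrays, with a bar for each group's mean (n = 3). Thbs1 lay lower and Thbs2 higher on every null array than on any wild-type array, whereas Acta2, Cnn1 and Tagln overlapped between the groups.

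The TGF-beta pathway was examined because TSP1 is a known activator of latent TGF-beta. The 19 pathway genes rose as a list by 0.19 (SE 0.05), 14 positive and 5 negative (camera adjusted p = 0.0398, or adjusted p = 0.514 with an estimated correlation). The latent TGF-beta binding proteins Ltbp2 and Ltbp3 had differences of 0.47 (SE 0.12) and 0.45 (SE 0.12), and Tgfb1 had -0.58 (SE 0.25, adjusted p = 0.466), or -0.32 without the third null array and -0.059 with the macrophage list as a covariate, a term added after the data were seen. No pathway gene passed over all genes, and 0 passed adjusted over the list alone. The list was called in 8 of 18 alternatives, and the call was lost without the first or second null array and without the second or the third wild-type array, at shifts of 0.16 to 0.21. TGF-beta target genes were not called (mean 0.10, SE 0.15, 19 genes, adjusted p = 0.225). Among them Id2, a transcriptional inhibitor, had a difference of -0.79 (SE 0.15) and was the only member to pass adjusted over the list alone, while 0 passed over all genes. Thrombospondin relatives and receptors were not called either (mean 0.02, SE 0.12, 16 genes, adjusted p = 0.174). Their median was 0.14, with 12 positive and 4 negative, and their member Cd36 had -1.33 (SE 0.55). There 3 members passed adjusted over the list alone and 0 over all genes. They were Thbs2 and Thbs3, with higher means in the null group, and the integrin subunit gene Itga4, at -1.42 (SE 0.37). Its signals on the null arrays were 7.06, 7.65 and 6.20, lowest on the third, as for the macrophage markers.

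Basement membrane genes rose, with all 20 measured members positive and a mean difference of 0.48 (SE 0.06). Camera called the list at an adjusted p of 5.42e-09, and it gave an adjusted p of 0.362 with an estimated correlation. Adjusted over the list alone, 4 members passed, and 0 passed over all genes. They were Agrn (agrin, 0.79, SE 0.14), Col18a1 (0.55, SE 0.12), Lamb1 (a laminin chain, 0.40, SE 0.10) and Col15a1 (0.85, SE 0.25). On the null arrays the list lay at 0.32, 0.24 and 0.16 around its mean over the 6 arrays, and on the wild-type arrays at -0.30, -0.21 and -0.20. The exact permutation p of the list mean was 0.1, two-sided, the smallest that 3 arrays against 3 can give. Fibrillar collagen and matrix genes rose by 0.30 (SE 0.16), 18 of 22 positive (camera adjusted p = 5.36e-06, or adjusted p = 0.477 with an estimated correlation). Around its mean over the 6 arrays this list lay at 0.10, 0.28 and 0.07 on the null arrays and at 0.12, -0.35 and -0.22 on the wild-type arrays, so the groups overlapped (exact permutation p = 0.3, two-sided). Fibroblast markers, which share Col1a1, Col1a2, Col3a1, Dcn and Lum with it, were also highest in their groups on the second null (0.25) and the first wild-type array (0.58). Adjusted over the list alone 9 passed, and 0 over all genes: Col1a1, Col1a2, Col3a1, Col5a1, Col5a2, Col6a1, Col6a3, Fbln2 and Loxl1. Col5a2 had the smallest p among them, with 11.25 ± 0.21 against 10.26 ± 0.21 (SD, n = 3), and Col3a1 the largest difference (1.03, SE 0.27). Without the second wild-type array the shift of this list was 0.20. Col5a1 and Col1a2, which have 2 probe sets each, differed by 0.68 and 0.51. Over the alternatives they went down to 0.37 and 0.32. Matrix proteases and their inhibitors were not called (mean 0.07, SE 0.07, 25 genes, adjusted p = 0.335, 0 passing either way). Their mean ran from 0.026 to 0.13 when an array was left out. Plat, tissue plasminogen activator, had a difference of 0.93 (SE 0.23), and Mmp23 had 0.62 (SE 0.18).

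Glycolysis and hypoxia genes rose by a mean of 0.78 (SE 0.21), with 16 of 17 members positive. Camera gave an adjusted p of 1.64e-11, and an adjusted p of 0.514 with an estimated correlation. Adjusted over the list alone 11 members passed, and 0 over all genes. They were Slc2a1 (the glucose transporter of most cultured cells), Pfkl, Pgk1, Ldha, Tpi1, Pdk1 (a kinase that holds back pyruvate dehydrogenase), Bnip3, Egln3 (a prolyl hydroxylase induced in hypoxia), Ndrg1, Ero1a and P4ha1. Egln3 measured 9.81 ± 0.99 against 7.53 ± 0.26 (SD, n = 3), a 4.86-fold difference, and Ero1a 12.53 ± 0.27 against 11.66 ± 0.11. Slc2a1 differed by 1.05 (SE 0.20, adjusted p over all genes 0.25). The null arrays were uneven. Around its mean over the 6 arrays the list lay at 0.61, -0.03 and 0.59 on the null arrays and between -0.43 and -0.36 on the wild-type arrays, and the second null array, the lowest of its group here, had the highest macrophage marker level of the null group.

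Macrophage markers fell by a mean of 1.39 on the log2 scale (SE 0.76, 2.61-fold), with all 20 genes lower in the null group. Camera called the list (adjusted p = 1.64e-11), and its adjusted p was 0.595 with an estimated correlation. Neither over all genes nor adjusted over the list alone did a member pass (0 in each), and 13 had an unadjusted p under 0.05. Cd68, a lysosomal protein of macrophages, measured 11.17 ± 1.33 in the null arrays and 12.77 ± 0.28 in the wild-type arrays (SD, n = 3), and Tyrobp, a myeloid signalling adaptor, 8.34 ± 1.34 against 10.05 ± 0.54. Around its mean over the 6 arrays the list lay at -0.40, 0.39 and -2.07 on the null arrays and at 0.23, 0.84 and 1.00 on the wild-type arrays, so the groups overlapped (exact permutation p = 0.2, two-sided). The size rested on the third null array, since without it the shift was -0.70, with Cd68 at -0.84 and Tyrobp at -0.97.

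**Figure D3:**
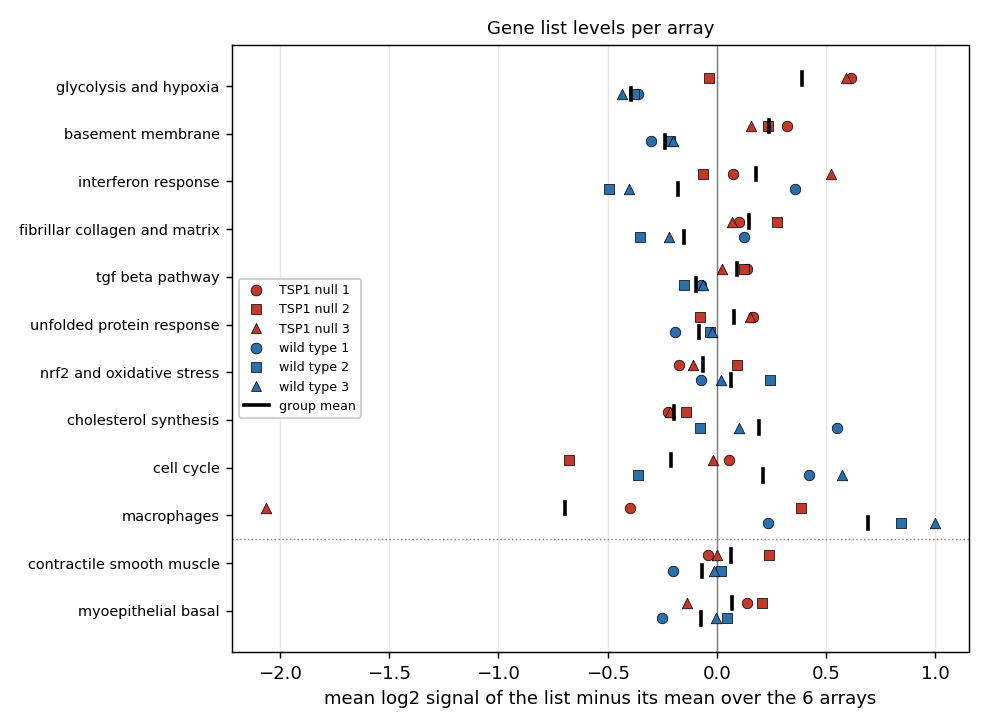
Mean log2 signal of each gene list on each array, minus the list's mean over the 6 arrays, with a bar for each group's mean (n = 3). The 10 lists called by camera stand above the dotted line and 2 lists that were not called below it, and the third null array lay at -2.07 for macrophage markers.

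Other cell types gave smaller shifts than macrophages, and with all 6 arrays camera called none of their lists. Several of these lists were dim, so small shifts do not show that the cell types were unchanged. Mean levels on the null and wild-type arrays were 5.00 and 5.22 for lymphocyte, 5.12 and 5.24 for acinar and 5.31 and 5.34 for skeletal muscle markers. They were 5.47 and 5.30 for ductal and 5.47 and 5.64 for endothelial markers, near the array median, against 8.75 and 10.13 for macrophage markers. With 1 array left out camera called fibroblasts at 0.44 and endothelium at -0.31 (without the first wild-type array), adipocytes at -0.33 (without the second null array), ductal markers at 0.24 (without the third null array) and acinar markers at -0.15 (without the first null array). Over the 6 fits that leave out 1 array, shifts ran from -0.086 to 0.44 for fibroblasts, -0.31 to -0.056 for endothelium, -0.33 to 0.021 for adipocytes, 0.052 to 0.24 for ductal, -0.15 to -0.10 for acinar, 0.18 to 0.37 for pericyte, -0.19 to -0.068 for Schwann cell and -0.11 to 0.034 for skeletal muscle markers. It also called fibroblasts at 0.22 with array weights. Fibroblast markers shifted by 0.12 (SE 0.34, 18 genes, adjusted p = 0.16), and the 3 members that passed adjusted over the list alone, Col1a1, Col1a2 and Col3a1, are also in the fibrillar matrix list. Acinar markers shifted by -0.12 (SE 0.04, 14 genes, adjusted p = 0.139), and Dcpp1 and Dcpp3, of a family of secreted proteins first described in mouse salivary gland, passed adjusted over the list alone at -0.88 (SE 0.23) and -0.76 (SE 0.13). The 6 arrays read Dcpp1 at log2 signals of 4.34 to 5.91 and Dcpp3 at 4.71 to 5.73, near the array median. Ductal and luminal epithelial markers shifted by 0.17 (SE 0.15, adjusted p = 0.192), with Cldn4 at 0.67 (SE 0.21) and Krt8 at 0.35 (SE 0.16), or 0.18 without the first null array. Lymphocyte markers had a mean of -0.22 (SE 0.13, adjusted p = 0.228) and a median of -0.05, and the mean ran from -0.30 to -0.11 when an array was left out, lowest in size without the third null array. Ptprc, which encodes CD45 of all leukocytes, had -1.84 (SE 0.64), or -1.07 without that array. Endothelial markers shifted by -0.17 (SE 0.16, adjusted p = 0.188), with Kdr at -0.55 (SE 0.18) and Pecam1 at -0.38 (SE 0.15), or -0.25 without the second wild-type array. Pericyte markers had a mean of 0.27 (SE 0.14, adjusted p = 0.275) and a median of 0.11. Ndufa4l2 at 1.96 (SE 0.52) carried the mean, since the other 9 members averaged 0.080, Notch3 at 0.73 (SE 0.23) among them. Its signals on the null arrays were 10.56, 9.20 and 10.40, lowest on the second, as for the glycolysis and hypoxia list. Schwann cell and nerve markers shifted by -0.13 (SE 0.09, adjusted p = 0.16) and skeletal muscle markers by -0.03 (SE 0.09, adjusted p = 0.543). Adipocyte markers had a mean of -0.10 (SE 0.25, adjusted p = 0.652) and a median of 0.02, with the scavenger receptor Cd36, which macrophages also express, at -1.33 (SE 0.55), or -0.69 without the third null array. Members of the fibroblast and acinar lists aside, 0 passed adjusted over the list alone, and in every one of these lists 0 passed over all genes.

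Cell cycle genes fell by a mean of 0.42 on the log2 scale (SE 0.37), with 27 of 29 members lower (camera adjusted p = 1.79e-06, or adjusted p = 0.595 with an estimated correlation). Mki67, the proliferation antigen Ki-67, had a difference of -1.03 (SE 0.29) and Bub1, a mitotic checkpoint kinase, -1.05 (SE 0.34). No member passed over all genes, and 0 passed adjusted over the list alone. The list varied within both groups, from -0.68 to 0.06 on the null arrays and from -0.36 to 0.57 on the wild-type arrays, and its shift was -0.19 without the second null array, -0.24 without the third wild-type array and -0.71 without the second. Without the second null and the first wild-type array together, a fit added after the data were seen, the shift was -0.084 and the call was lost (adjusted p = 0.306, against 6.06e-17 to 0.595 over all alternatives). Cholesterol synthesis genes fell by a mean of 0.39 (SE 0.19), with 12 of 15 members lower (camera adjusted p = 6.06e-06, or adjusted p = 0.595 with an estimated correlation). Fdps and Msmo1, enzymes of the pathway, and Insig1, which holds back its transcriptional activation, passed adjusted over the list alone, at -0.70 (SE 0.16), -0.70 (SE 0.19) and -0.67 (SE 0.17), while 0 passed over all genes. Without the first wild-type array the shift was -0.21. Genes of the oxidative stress response fell by 0.13 (SE 0.12), with 13 of 18 lower (camera adjusted p = 0.0398, or adjusted p = 0.595 with an estimated correlation). Cat, which encodes catalase, was their only member to pass adjusted over the list alone (-0.75, SE 0.16), with 0 over all genes, and Gsta4 had -0.46 (SE 0.22), or -0.24 without the first wild-type array. This list was called in 11 of 18 alternatives, and the call was lost without the first null (-0.07), the third null (-0.11) or the second wild-type array (-0.04). Its shift was -0.21 without the second null array and -0.20 without the first wild-type array.

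Interferon response genes rose by a mean of 0.36 (SE 0.32), with 20 of 24 members positive (camera adjusted p = 0.0368, or adjusted p = 0.672 with an estimated correlation). Irf7, a transcription factor of the response, had a difference of 0.66 (SE 0.18), whereas Rsad2, an antiviral enzyme, had -0.38 (SE 0.10), and 0 passed over all genes or adjusted over the list alone. Around its mean over the 6 arrays the list lay at 0.07, -0.06 and 0.52 on the null arrays. On the wild-type arrays it lay at 0.36, -0.49 and -0.40, so the groups overlapped. The level was highest on the third null array, the array with the lowest macrophage markers. It was next highest on the first wild-type array, where macrophage markers lay above their mean (0.23). With the macrophage list as a covariate the mean shift was -0.09 and the call was lost. Without the first wild-type array the shift was 0.63, and the call was also lost without the third null (0.18), the second wild-type (0.20) or the third wild-type array (0.25). It was lost with dim probe sets left out too (0.40, camera adjusted p = 0.201), and stood in 12 of 18 alternatives. Unfolded protein response genes rose by 0.16 (SE 0.10), 15 of 16 positive (camera adjusted p = 0.0327, or adjusted p = 0.595 with an estimated correlation), with 0 members passing over all genes and 0 adjusted over the list alone. Trib3, a stress-induced pseudokinase, had a difference of 0.72 (SE 0.22), and the transcription factor Atf3 had -0.67 (SE 0.28), or -0.41 without the third wild-type array. That list was called in 12 of 18 alternatives, and the call was lost without the first null (0.12), the third null (0.13) or the first wild-type array (0.11).

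The remaining lists were not called. Cytokines and NF-kappaB targets shifted by 0.05 (SE 0.06, 27 genes, adjusted p = 0.637), with Il6 at 0.62 (SE 0.15) and the neutrophil chemokine Cxcl1 at 0.98 (SE 0.26). Their shift ran from 0.020 to 0.095 when an array was left out. Antigen presentation genes shifted by -0.01 (SE 0.07, 17 genes, adjusted p = 0.375), with Cd40 at -0.60 (SE 0.17) and Tap2 at 0.49 (SE 0.15). Complement genes had a mean of -0.34 (SE 0.37, 13 genes, adjusted p = 0.0842) and a median of 0.02. Camera called this list without the second null array (-0.64), without the third wild-type array (-0.46) and with dim probe sets left out (-0.60), and its shift ran from -0.64 to -0.14 when an array was left out. Their member Cd59a passed adjusted over the list alone, and C3ar1, a complement receptor of myeloid cells, had -1.66 (SE 0.64), or -0.88 without the third null array and -0.061 with the macrophage list as a covariate. Genes of the p53 response and senescence shifted by 0.11 (SE 0.18, 15 genes, adjusted p = 0.362), and were called at 0.24 without the second wild-type array, but the shift was -0.011 without the first wild-type array. The stress-induced Sesn2 passed adjusted over the list alone at 0.81 (SE 0.13), and Sesn1 had -0.70 (SE 0.21), or -0.46 without the third null array. Progenitor markers had a mean of 0.05 (SE 0.02, 16 genes) while camera gave the direction as down (adjusted p = 0.907), with Msi1 at 0.33 (SE 0.15) and Fgf10 at -0.34 (SE 0.18), or -0.14 without the first null array. In each of these lists 0 genes passed over all genes tested, and apart from Cd59a and Sesn2 0 passed adjusted over the list alone.

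In all, camera with its preset correlation called 10 of 30 lists, 6 higher and 4 lower. With a correlation estimated for each list it called 0, with 2 lists at an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move on balance one way, called 0 lists, with 6 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0792. These were the basement membrane, fibrillar matrix, glycolysis and hypoxia and TGF-beta pathway lists, and the matrix protease and cytokine lists, which camera did not call. The other lists that camera called, macrophages included, were not among them. Other divisions of the 6 arrays into 3 and 3 gave up to 13 lists by camera. Both of the following fits were added after the data were seen. With the macrophage list as a covariate, camera also called the basal epithelial (0.37), calcium signalling (0.15), thrombospondin (0.24), p53 (0.34), ductal (0.28) and pericyte lists (0.43), and the interferon response (-0.093), unfolded protein response (0.098) and oxidative stress lists (-0.019) lost their calls. Under this fit 26 of 84 named genes moved by over 1.5 times or turned. Cd68 (-0.19) and Tyrobp (-0.19) did so by construction, as members of the macrophage list. Others were Ptprc (-0.26), Cd36 (0.011), Sesn1 (-0.24), Cd40 (-0.33), Kdr (-0.25), Dcpp1 (-0.40), Atf3 (-0.29), Irf7 (0.33), Cxcl1 (0.51), Plat (0.54), Krt17 (1.32), Notch3 (1.24) and Ndufa4l2 (1.15). Without the second null and the first wild-type array together, camera also called fibroblasts (0.34) and adipocytes (-0.43), and the TGF-beta pathway lost its call (0.19). The exact permutation p of the list mean was 0.1, the smallest possible, for 6 lists. These were the basement membrane, glycolysis and hypoxia, cholesterol synthesis and TGF-beta pathway lists, and the progenitor and acinar lists, which camera did not call. The same p was 0.2 for macrophages, 0.3 for fibrillar matrix, cell cycle, interferon and unfolded protein response, and 0.4 for oxidative stress. As a check of the samples, Xist measured 10.7 to 11.2 and the 3 Y-linked genes 3.07 to 4.19 on the 6 arrays, all labelled female.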

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

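The test of the normalization was chosen only after the result was seen, whereas the count over other divisions of the arrays and the test over all deposited probe sets were planned.

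Among the deposited probe sets without a gene symbol, which the comparison of named genes leaves out, 2 differed sharply between the groups. Probe set 17549150 measured 10.56 ± 0.22 on the null arrays and 5.35 ± 0.06 on the wild-type arrays (SD, n = 3), a log2 difference of 5.21 or 37.0-fold, and probe set 17549062 measured 10.51 ± 0.29 against 5.50 ± 0.11, a difference of 5.01 or 32.3-fold. Tested with limma among all 41345 probe sets, their adjusted p values were 9.17e-05 and 0.000215, and the next largest difference of any probe set was 2.65 in size. They drew attention as a signal outside the main measurement that stood far above its level in the control arrays, where both lay near the array median.

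Normalization of a whole array, which moves probe sets of the same level alike, was examined as a cause for these probe sets. The other 2470 probe sets within 0.1 log2 units of either one on the wild-type arrays had a median difference of -0.011 (SD 0.30), and the highest was 1.48. The 2 differences were thus not shared by probe sets of the same level. The comparison had little left to decide, because the deposited values were already normalized across arrays. In addition, no other probe set differed by more than 2.65 in size. The 10 divisions of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real one called 2 probe sets and the highest other called 0, so only 1 of them gave as many. What these probe sets measure was not tested, because the probe sequences were not used here. The altered allele and DNA of another strain therefore stay open as explanations, and no biological explanation was tested. It is also open whether they are control probe sets, which could not be told from other unnamed ones.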

How the results depend on the processing

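Chosen only after the data were seen were the fit without the second null and first wild-type arrays together and the macrophage covariate. The count of 0 called genes (limma, 2341 at an unadjusted p under 0.05) was also 0 under quantile normalization, median centring, dim probe sets left out, averaged probe sets, an intensity trend with a robust prior, array weights, the 1.5-fold minimum, the ordinary model and the macrophage covariate. Testing every deposited probe set called 2, both higher, and neither has a gene name. Leaving out each array in turn gave 0 to 34 genes, 0 to 15 higher and 0 to 19 lower, with 34 reached without the second null array and 1 (Fabp7) without the first wild-type array. Without both of these, 2 arrays against 2, 365 genes passed, 145 higher and 220 lower. These arrays lie between the groups on the first principal component or apart on the second, so leaving them out lowers the spread by construction. Thbs1 stayed between -0.78 and -0.58, with adjusted p from 0.0749 to 0.827. Of the 200 neighbours of Thbs1, 0 passed, with 0 to 1 when an array was left out, 3 without both arrays and 0 with 50 or 200 genes on each side. Lists called higher and lower were 6 and 4. They were 3 and 5 without dim probe sets and 0 and 0 with an estimated correlation. With the macrophage covariate they were 11 and 2, where the macrophage list itself keeps no mean shift by construction. The contractile shift of 0.13 ran from 0.045 to 0.19 when an array was left out, called at 0.19 without the first null array. It was -0.023 without both arrays and 0.27, called, with the macrophage covariate. Its adjusted p over alternatives ran from 0.00542 to 0.797. With the replicate number as a replicate block, 0 genes passed and the contractile shift was 0.13 (adjusted p = 0.0979). Same-numbered arrays had residual correlations of -0.14, 0.18 and -0.16, which gave no common sign of pairing. With 3 arrays per group these values cannot exclude that a number marks something shared. The block changed no call of these counts.

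Direction turned in the settings below, and the cause was not tested. With all 6 arrays Cd36 was at -1.33, L1cam -0.54, interferon response 0.36, complement -0.34 and lymphocytes -0.22, and the other results named here lay between -0.17 and 0.14. Without dim probe sets, which tests fewer genes, the calcium signalling list was at -0.00423, antigen presentation at 0.11 and endothelium at 0.074. With array weights Cnn1 was at -0.00498, Oxtr at 0.028, calcium signalling at -0.026 and the thrombospondin list at -0.047. Without both arrays the basal epithelial list was at -0.018, calcium signalling at -0.12, thrombospondin at -0.13, matrix proteases at -0.00215 and p53 at -0.11. With the macrophage covariate Cd36 was at 0.011, L1cam 0.036, interferon response -0.093, antigen presentation 0.069, complement 0.00531, lymphocytes 0.000993, adipocytes 0.26, Schwann cells 0.010 and skeletal muscle 0.030. With each array left out, Cnn1 ran from -0.11 to 0.18, Oxtr from -0.21 to 0.077, Chrm3 from -0.14 to 0.12, calcium signalling from -0.058 to 0.077, thrombospondin from -0.071 to 0.11, TGF-beta targets from -0.035 to 0.18, p53 from -0.011 to 0.24, antigen presentation from -0.069 to 0.045, fibroblasts from -0.086 to 0.44, adipocytes from -0.33 to 0.021 and skeletal muscle from -0.11 to 0.034. Of the other values for named genes, 1435 kept direction and side of the threshold and 31 passed it. For the other lists the numbers were 438 and 19, and 35 lost their call. Camera on ranks called 5 lists higher and 4 lower. Signal near background limits Krt14, Krt17, Chrm3 and the Dcpp genes, whose log2 signals lay close to the array median. Other named genes were as dim, among them Mir5104 (3.59 to 5.40), Fgf10 (4.41 to 5.23), Kdr (4.94 to 6.04) and Exd1 (5.04 to 6.00). Mmp27 and P2ry13 also lay close to the median on the null arrays.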

Other observations

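The tests on macrophage markers, glycolysis and hypoxia genes and the neighbours of Thbs1 were chosen only after the result was seen, as were the genes and RNA classes named next, whereas the counts over other divisions of the arrays were planned.

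Folr2, a folate receptor of tissue macrophages, measured 8.31 ± 1.39 on the null arrays and 10.68 ± 0.30 on the wild-type arrays (SD, n = 3). Tlr7, an endosomal receptor for RNA, measured 6.62 ± 1.23 against 8.64 ± 0.10, and the scavenger receptor gene Msr1 8.77 ± 1.35 against 10.56 ± 0.65. Slc16a3, which encodes a lactate exporter, differed by 1.33 (SE 0.36), the oxygen-sensing hydroxylase gene Egln1 by 1.03 (SE 0.20), Ak4 by 1.12 (SE 0.22) and Ddit4, an inhibitor of mTOR signalling, by 1.28 (SE 0.20). The collagen-binding integrin gene Itga11 differed by 1.42 (SE 0.25). On the 6 arrays none of these genes passed limma's threshold over all genes tested (adjusted p from 0.19 to 0.40), and Folr2 and Slc16a3 were among the 34 that passed without the second null array.

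Small nucleolar RNAs, a class tested because Snora34 had the smallest p of all genes, had a mean difference of -0.18 over 78 members. Camera gave an adjusted p of 3.22e-05 with its preset correlation and an adjusted p of 0.74 with an estimated correlation. The class varied within groups, from -0.26 to 0.12 on the null arrays and from -0.03 to 0.26 on the wild-type arrays. MicroRNA genes (483) and ribosomal protein genes (86) had means of -0.02 and 0.04.

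For the lower macrophage markers, array scaling, which moves all genes of an array alike, is argued against as the whole cause. The deposited values were already normalized across arrays and had nearly equal quartiles. That left little to decide for the comparison of the contractile list with the markers. The list shifted by 0.13 (95% interval -0.18 to 0.44) and the markers by -1.39 (95% interval -3.49 to 0.72). Fewer macrophages in the null cultures is a candidate explanation. In the 19 expressed markers 1 component held 0.953 of the variance within groups. All 19 differed by -1.93 to -0.93, abundant ones such as Cd68, Lyz2 and Fcer1g included. Markers chosen for 1 cell type would also move together through lower expression per cell or 1 deviating array. The shared component therefore cannot tell fewer macrophages from these. The third null array supplies much of the size, and without it the difference was -0.70 (95% interval -2.04 to 0.64), too wide to tell whether the other arrays differ. Whether fewer macrophages were carried over from the gland by chance or the genotype acts on them was not tested, and counting them in matched cultures would be the test.

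For the higher glycolysis and hypoxia genes, a loss of macrophage RNA that raises the share of all other RNA would move contractile genes equally. The contractile list shifted by 0.13 (95% interval -0.18 to 0.44), below the 0.78 of the glycolysis and hypoxia list. The median of the 22 contractile members was 0.09 (SD 0.19) and the highest 0.42. These values argue against such a loss as the whole cause only if the 0.78 is taken as exact. The difference between both shifts, which carries the spread of both lists, was 0.65 (95% interval -0.21 to 1.51). That interval includes 0, so this explanation stays open, in whole or in part. With the macrophage level of each array as a covariate the difference of the list was 0.50 (95% interval -0.24 to 1.25). That interval includes 0, so with 6 arrays the macrophage level cannot be told apart from an effect of the genotype. Unequal oxygen or density between cultures was not measured and stays open as well.

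Divisions of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For genes called with limma the real value was 0 and the highest other 0, so all 10 gave as many. For genes at an unadjusted p under 0.05 the real value was 2341 and the highest other 2207, and 1 division, the real one, reached it. For lists called by camera the real value was 10 and the highest other 13, and 4 divisions reached 10. The division with both 2207 genes and 13 lists sets the first and the third null and the first wild-type array against the rest.

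Genes next to Thbs1, where a null allele made in another strain can keep that strain's DNA, showed an unadjusted p under 0.05 in 21 of 200 cases (10.5%), against 10.6% of the other 21979 genes. The odds ratio was 0.995 (Fisher's exact test, two-sided, 95% interval 0.600 to 1.57), and it was 0.838 (95% interval 0.371 to 1.66) with 50 genes on each side and 1.02 (95% interval 0.724 to 1.41) with 200. The genes of smallest p were placed differently. At an unadjusted p under 0.01 the odds ratio was 1.99 (95% interval 0.971 to 3.66). At an unadjusted p under 0.001 there were 5 of 200 neighbours (Exd1, D330050G23Rik, Ppip5k1, AV039307 and Rasgrp1) against 80 others, an odds ratio of 7.02 (95% interval 2.19 to 17.3), 8.29 with 50 genes on each side and 4.95 with 200. As many were held by 0.734% of all runs of 200 genes along the chromosomes, those overlapping this one included. DNA of another strain kept around the allele is therefore a candidate explanation for these few genes, as a hypothesis, since both thresholds were chosen after the values were seen. None of these 5 passed limma's adjusted threshold over all 22180 genes. Regulation in the null cells was not told apart from a variant under the probes, whose sequences were not used here.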
